A study of Mus musculus with 16 samples.

How the data were processed

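Poly(A) RNA of mouse ileum was sequenced in 16 libraries, 4 per group: breastfed, NEC, NEC with oral ST266 and NEC with intraperitoneal ST266. Per the labels, the libraries were strand-specific by dUTP incorporation, mice of the 3 NEC groups were fed by gavage 5 times a day, and ST266 was given at 20 µL per day. The wording of the oral dose in the labels is ambiguous, and they give 2 feeding volumes, 40 and 50 µL per g. CASAVA, cutadapt 1.9, FastQC 0.11.9, Salmon 1.3.0, DESeq2 1.32.0 and the build mm10 are named per the submitters' processing notes, and their settings, as well as the step from transcripts to genes, are not given in the sources used here.

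The deposited count table holds expected counts, which are estimated read counts per gene symbol rounded by the authors to whole numbers. A second deposited table holds log2 values, which the sums per column show to be log2 of TPM plus 1 from the authors. The deposited per-sample Salmon files hold expected counts and TPM (transcript abundance scaled to library and length) for 117135 transcripts each, of which 99.0% matched GENCODE M21. Totals of the count table equalled the sums of the Salmon files within 155 reads in every library, and 98.7% of genes were equal within 1 count after transcripts were summed by gene. The tests used the count table, the Salmon files served as an alternative, and the log2 table was only checked.

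Of 21711 entries in the count table, 2953 had no gene name and held 1.08% to 1.49% of the counts of a library, without a group difference from breastfed beyond the spread. These were left out, 27 repeated symbols were summed, and 18730 named genes remained. Genes with enough counts for a test were kept by filterByExpr of edgeR with the groups as design, which left 15101 genes and removed 3629. At this depth the biological coefficient of variation was 13.3% and the median SE of a log2 change between NEC and breastfed was 0.12.

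Each gene was tested in R 4.3.3 with edgeR 4.0.16 by the quasi-likelihood F test (robust fit, TMM scaling), with all 16 libraries in 1 fit of 4 group means and 12 residual degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested within each of 7 comparisons, and a gene was called at an adjusted p under 0.05. Errors are standard errors of the log2 change unless SD is stated, and levels are counts scaled to library size (CPM) with TMM factors. Replicate numbers were not taken to pair libraries: of 24 correlations between libraries of the same number in different groups 6 were over 0.1 and 8 were the best of their group.

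The 41 gene lists (702 symbols, 684 found, 1 of them through a synonym) cover pathways, cell types, other tissues, other gut regions and RNA quality or handling. They were tested with camera of limma 3.58.1 on log2 CPM (preset correlation 0.01, two-sided, adjusted over the 41 lists per comparison), with camera at an estimated correlation and fry beside it. Camera compares the members of a list with all other genes, and fry asks whether members move on balance in 1 direction or, in its mixed form, in either. For each list the members called over all genes and those called when adjusted over the list alone were counted.

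The axis score uses log2 CPM (prior count 2) of the genes called between breastfed and NEC. It is the mean over these genes of the difference from the breastfed mean, signed by the direction of the NEC change. This mean was divided by the mean signed change from breastfed to NEC, so that each gene counts alike before scaling. Breastfed and NEC libraries were scored on axes made without them, and ST266 libraries on the mean of the axes that leave out each NEC library. Differences were tested by a two-sided exact permutation over 70 assignments and adjusted over both routes. Return toward the breastfed level and agreement between routes were computed over the 6 ordered halvings of the NEC libraries, so that 1 NEC library never served both sides, beside 20 simulations without an ST266 effect. The permutation over 17325 assignments for the agreement was added after the data had been seen.

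Groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names, for each comparison with at least 20 calls and for both routes against NEC, the 6 largest rises and falls among called genes with an assigned name, a mean log2 CPM of at least 2 and no overlap between groups, up to 3 members of each list with at least 3 called members, and 14 fixed genes. It named 116 genes for NEC against breastfed, more than the about 30 foreseen, and these are given in short form. Other members of lists with 5 or fewer calls, the 4 genes called with intraperitoneal ST266, and the clock genes were chosen after their values were seen. Some genes that the rule or a list names are not reported here.

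Alternatives were DESeq2 size factors, no low-count filter, a mean CPM of at least 1, DESeq2 1.42.0, limma-voom with quality weights, only the compared groups, the replicate number as a block, each library left out in turn, a fold change of 1.5 as the null (glmTreat), removal of genes holding over 1% of the counts, and sums of the Salmon files. On simulated data with 200 changed genes, edgeR recovered 68.7% of 1.5-fold, 71.2% of 2-fold and 98.5% of 4-fold changes between oral ST266 and NEC, with 4 false calls where DESeq2 had 19. Between intraperitoneal ST266 and NEC it recovered 64.2%, 81.8% and 95.5%. Each comparison rested on a single simulation with its own draw of changed genes, and genes were drawn independently of each other. These shares are therefore rough, do not rank the comparisons, and leave out correlation between genes as in the measured data. Gene positions come from GENCODE M21. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.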

Results

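Gene expression was measured by RNA sequencing in the ileum of C57BL/6 mice at postnatal day 11, in 4 groups of 4 libraries each. One group was breastfed, and the other 3 went through a protocol that induces experimental necrotizing enterocolitis (NEC), an inflammatory bowel disease of preterm infants. That protocol joined gavage feeding of formula, bacteria grown from faeces of a severely ill human patient, and hypoxia at 5% oxygen for 10 minutes, 2 times a day for 4 days. Of these 3 groups, 1 had no further treatment and 2 received ST266, the secretome of amnion-derived multipotent progenitor cells, either in the formula (oral) or by intraperitoneal injection. No group is labelled as given an injection or a carrier without ST266, so effects of these cannot be told apart from those of ST266. Total counts per library ran from 12581011 to 17654587, and 16896 to 17377 named genes had at least 1 count. The labels do not state whether each library came from a separate animal, so the p-values below measure only the spread between these samples.

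Breastfed libraries stood apart from all others on the first principal component, which held 39.6% of the variance: they lay between -68.5 and -33.8, and the 12 libraries of the NEC protocol between -1.11 and 37.6. Breastfed replicate 1 lay farthest out, at -68.5. Across genes, pairs of libraries of the same group correlated at 0.968 to 0.988 and pairs from different groups at 0.926 to 0.987, where genes are not independent replicates.

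How the disease protocol alters the ileum was asked by comparing NEC with breastfed mice. Among called genes with an assigned name, a mean log2 CPM of at least 2 and no overlap between the groups, the largest rises were in genes of host defence and bile acid uptake. Reg3g, a secreted antimicrobial lectin (chromosome 6, 78466269 to 78468872, mm10), rose from 4.41 ± 2.63 to 108 ± 49.1 CPM (counts scaled to library size, SD, n = 4), a log2 change of 4.61 (SE 0.88, adjusted p = 0.00115). Saa3, an acute-phase protein (chromosome 7, 46711998 to 46715700), rose by 4.51 on the log2 scale (SE 0.69, adjusted p = 0.000192), and Slc10a2, the bile acid transporter of the ileal brush border (chromosome 8, 5083219 to 5105351), by 3.90 (SE 0.45, adjusted p = 1.73e-05). Fabp6, which binds bile acids inside enterocytes, rose by 4.19 and Reg3b by 3.75, and the glutathione transferase Gstm3 followed. Among the same genes the largest falls were in the fetal serum protein Afp (chromosome 5, 90490737 to 90508907), from 411 ± 114 to 64.3 ± 9.81 CPM (log2 change -2.68, SE 0.20, adjusted p = 2.09e-07), and in Notum, which inactivates Wnt proteins, at -2.47. Next came the erythroid genes Alas2 at -2.24, Hba-a1 at -2.18, Hba-a2 at -2.17 and Hbb-b1 at -2.16. Reads of such closely related genes (Reg3, Saa, globin and defensin families) can be assigned to the wrong member, so their single values are less certain than their shared direction. Of 15101 genes tested with edgeR, 6642 were called (3344 higher, 3298 lower), with a median absolute log2 change of 0.49, and 878 of these changed more than 2-fold (483 higher, 395 lower). When the test asked for a change beyond 1.5-fold, 580 genes were called, 411 of them higher.

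**Figure D1:**
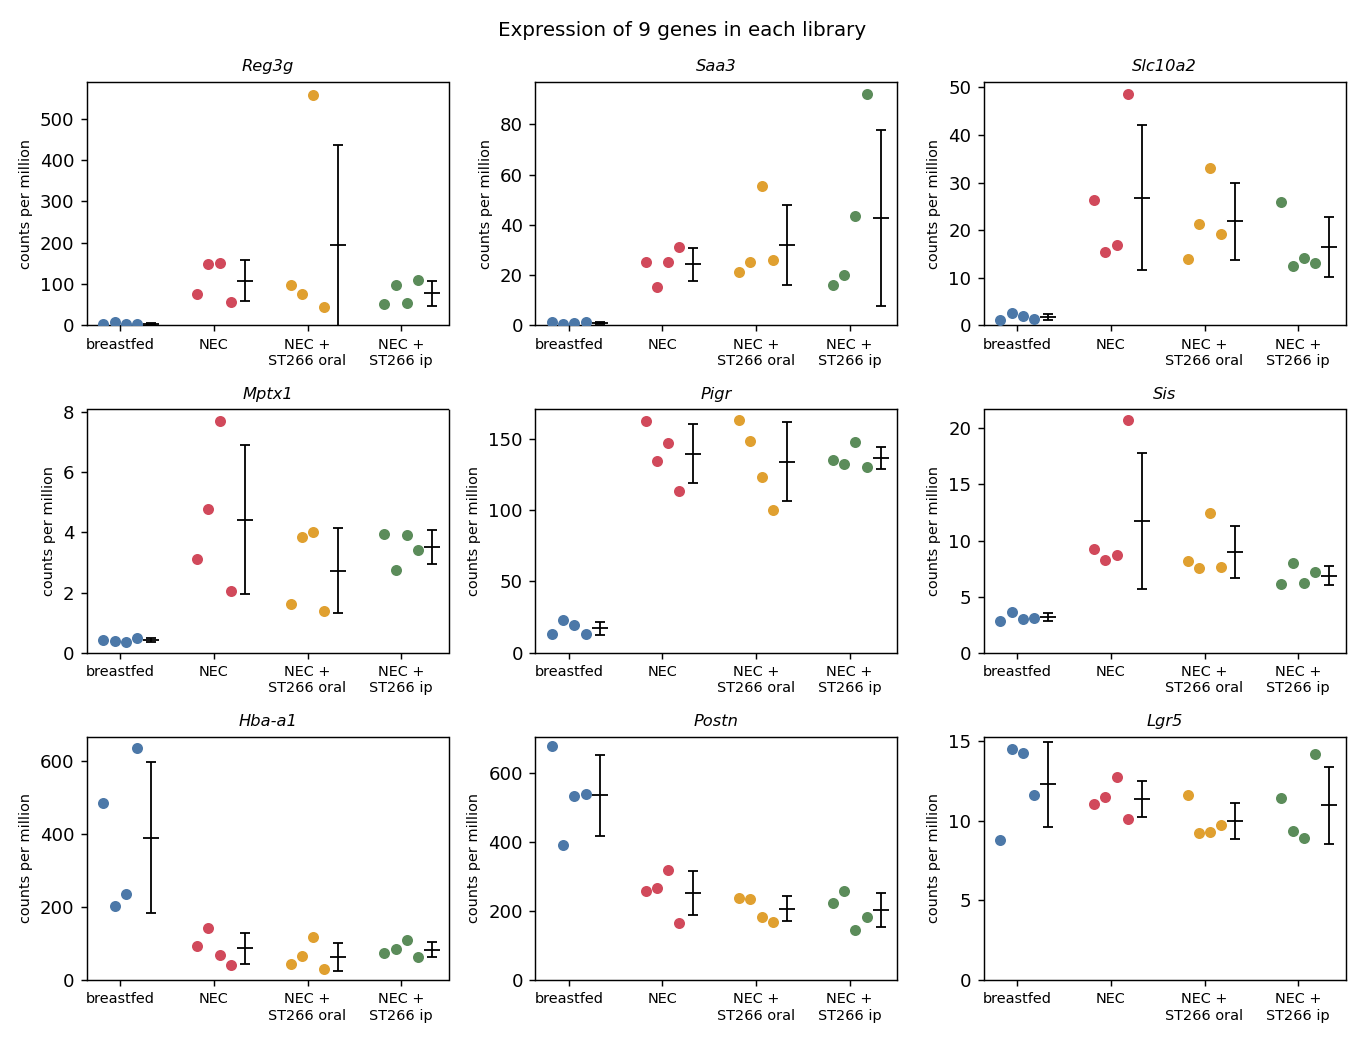
CPM of 9 genes (vertical axes, from 0) in each of the 16 libraries, by group (points), with the mean and SD of 4 libraries beside them, where an SD bar that would pass below 0 is clipped. Reg3g rises from a mean of 4.41 in breastfed to 108 in NEC mice, and the 4 NEC libraries of Pigr lie above all breastfed ones.

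Defence and secretory genes of the epithelium rose together. All 13 measured Paneth cell genes rose (13 adjusted over the list alone, median log2 change 2.75), among them Mptx1 by 3.40 (SE 0.46), the protease Mmp7 by 2.75 (SE 0.52) and the defensin Defa22 by 3.01 (SE 0.57). The list differed from other genes by camera (adjusted p = 7.54e-05), but not with its own gene correlation (adjusted p = 0.488 with an estimated correlation). Of 17 antimicrobial defence genes 11 rose and 0 fell (11 adjusted over the list alone, median 1.67), including Pigr, which carries antibodies across the epithelium, by 3.04 (SE 0.18, adjusted p = 4.07e-08), and Duox2, an oxidase that makes hydrogen peroxide, by 3.15 (SE 0.34). Their camera adjusted p = 0.000169 became an adjusted p = 0.442 with an estimated correlation. Goblet cell genes rose in 11 of 15 cases (12 adjusted over the list alone, median 1.17), with Agr2 up by 2.66 (SE 0.21), Clca1 by 2.66 (SE 0.32), Tff3 by 1.36 (SE 0.24) and the mucin Muc2 by 1.41 (SE 0.25). Here camera gave an adjusted p = 0.000153, and an adjusted p = 0.442 with an estimated correlation. Of the 41 lists, camera called 23 between NEC and breastfed mice, and 0 with an estimated correlation. Fry, which does not set members against other genes, called 25 in 1 direction (smallest adjusted p = 3.69e-05).

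Genes of absorption and digestion rose as well. In the list of bile acid handling 10 of 13 members rose (10 adjusted over the list alone, median 0.92, camera adjusted p = 5.62e-05). Among them was Cyp3a13 at 0.92, and the list had an adjusted p = 0.442 with an estimated correlation. Brush border enzymes and transporters rose in 13 of 21 cases (15 adjusted over the list alone, median 0.78, camera adjusted p = 2.47e-05). The proteases Mep1b at 1.18 (SE 0.14) and Anpep at 1.43 (SE 0.20) were among them, and the list had an adjusted p = 0.488 with an estimated correlation. Breastfed 1 stood apart with the lowest score of this list, 6.65 against 7.29 to 7.41 in the other breastfed libraries. Sis, the sucrase-isomaltase that marks enterocytes after weaning, rose by 1.89 (SE 0.27), from 3.16 ± 0.349 to 11.8 ± 6.04 CPM. NEC 4 stood apart in Sis at 20.8 CPM (8.27 to 9.28 in the other NEC libraries) and raised that mean. Counting Sis, 6 of 8 adult-type enterocyte genes rose (7 adjusted over the list alone, median 1.01, camera adjusted p = 0.000967). Bcl2l15 at 1.38 and Ces2c at 1.41 were examples, and the list had an adjusted p = 0.442 with an estimated correlation. Lipid absorption genes rose in 13 of 19 cases and fell in 2, Cd36 and Scarb1 (14 and 2 adjusted over the list alone, median 0.56, camera adjusted p = 0.000763, adjusted p = 0.488 with an estimated correlation). Among them the lipoprotein gene Apoc2 rose by 2.24 (SE 0.28) and the fatty acid binding protein Fabp2 by 1.83 (SE 0.27). Fabp1 reached 2.26 ± 1.13 CPM in NEC and 0.0917 ± 0.0775 CPM in breastfed mice, a level of few counts. Of 8 markers of the proximal small intestine 5 rose (Fabp1, Gsta1, Rbp2, Cyp3a11 and Apoa4, 5 adjusted over the list alone, median 1.12, camera adjusted p = 0.00693). Gsta1 rose by 2.56 and Rbp2 by 1.55, and the list had an adjusted p = 0.442 with an estimated correlation. That call ended when only genes with a mean CPM of at least 1 were kept (median 0.56, adjusted p = 0.0765). Among 17 genes of the vacuolated enterocytes of the neonatal ileum, Tmigd1 rose by 1.78, Clec2h by 1.36 and Cubn by 0.82, while Ctsl, Folr1 and Nox4 fell (3 and 3 adjusted over the list alone, median 0.06, camera adjusted p = 0.483).

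Stress defence and mitochondrial metabolism genes were higher in NEC mice. In the list that joins oxidative stress genes with targets of NRF2, a regulator of that response, 19 of 20 genes rose (19 adjusted over the list alone, median 0.76, camera adjusted p = 5.27e-07). They included the metallothionein Mt1 at 1.75 (SE 0.20), Gstm1 at 1.18 (SE 0.14) and superoxide dismutase Sod1 at 0.63 (SE 0.07), with adjusted p = 0.442 with an estimated correlation. Fatty acid oxidation genes rose in 14 of 23 cases (15 adjusted over the list alone, median 0.44, camera adjusted p = 1.93e-05, adjusted p = 0.488 with an estimated correlation). Vnn1 at 2.21 (SE 0.16), Acadvl at 0.60 and Cpt2 at 0.76 were among them. Breastfed 1 stood apart with the lowest score of this list, 6.066 against 6.415 to 6.438 in the other breastfed libraries. Oxidative phosphorylation genes rose in 18 of 24 cases (18 adjusted over the list alone, median 0.25, camera adjusted p = 2.47e-05, adjusted p = 0.488 with an estimated correlation). Cox5a rose by 0.69 and Cyc1 by 0.38. The median of this list fell to 0.09 once a trend of the fold changes with GC content and gene length was removed. Its score stood apart in 2 libraries, both in the direction of the rise. Breastfed 1 was lowest at 7.231 (7.347 to 7.361 in the other breastfed libraries) and NEC 4 highest at 7.723 (7.496 to 7.518 in the other NEC libraries). Transcripts encoded by mitochondrial DNA, a list that can also reflect RNA handling, rose in 10 of 13 cases (12 adjusted over the list alone, median 0.46, camera adjusted p = 0.000169, adjusted p = 0.488 with an estimated correlation). ATP6 rose by 0.60 and CYTB by 0.51. In the hypoxia list 10 of 20 genes rose and Pdk1 fell (11 and 1 adjusted over the list alone, median 0.36, camera adjusted p = 0.00309, adjusted p = 0.442 with an estimated correlation). The growth factor Vegfa rose by 0.76 and Ero1a by 0.75. In the unfolded protein response list 12 of 20 genes rose (13 adjusted over the list alone, median 0.43, camera adjusted p = 0.00461, adjusted p = 0.488 with an estimated correlation). Xbp1, a transcription factor of that response, rose by 0.83. Its 2 members that fell were Trib3 at -2.07 and Chac1 at -2.74.

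Inflammatory signalling genes moved in both directions. In the TLR4 and NF-kB list 8 of 22 genes rose, among them the inhibitors Nfkbia at 0.74 and Tnfaip3 at 0.99, while Traf6 at -0.75 and Tlr9 at -1.60 fell (8 and 2 adjusted over the list alone, median 0.12, camera adjusted p = 0.169). Of 21 cytokine and chemokine genes 9 had enough counts to test, and 3 rose (1 adjusted over the list alone, median 0.37, camera adjusted p = 0.372): Il1rn, which blocks the interleukin 1 receptor, at 1.15, Ccl7 at 2.27 and Il18 at 0.49. Il18 passed by a small margin (adjusted p = 0.0449) and was lost in 7 of 8 fits that left out 1 library, with adjusted p of 0.0546 (without breastfed 2) to 0.11 (without breastfed 1), and was kept without NEC 1. Ccl7 (adjusted p = 0.0413) was also lost in 7 of 8, with adjusted p of 0.0513 (without breastfed 3) to 0.119 (without NEC 3), and was kept without NEC 4. Interferon response genes fell in 7 of 24 cases (7 adjusted over the list alone, median -0.54, camera adjusted p = 0.0177, adjusted p = 0.686 with an estimated correlation). Ifit1 was at -1.38 and Psmb9 at -0.96. Cell death genes rose in 8 of 20 cases, with the pore-forming Gsdmd at 0.68 and Ripk3, a kinase of necroptosis, at 0.78, and fell in 3, Bbc3 and Bcl2l11 among them (11 and 3 adjusted over the list alone, median 0.21, camera adjusted p = 0.10). Breastfed 1 stood apart with the lowest score of the cell death list, 4.28 against 4.59 to 4.64 in the other breastfed libraries. Genes of epithelial repair rose in 12 of 19 cases and Egfr fell (12 and 1 adjusted over the list alone, median 0.64, camera adjusted p = 0.00461, adjusted p = 0.442 with an estimated correlation). The protease Mmp10 rose by 2.11 and keratin Krt7 by 1.08. Junction genes rose in 10 of 19 cases and Mylk fell (11 and 1 adjusted over the list alone, median 0.27, camera adjusted p = 0.000763, adjusted p = 0.488 with an estimated correlation). Tjp3 rose by 0.62 and Cgn by 0.72. Immediate early genes, which can also respond to handling, rose in 8 of 17 cases and Dnajb1 fell (8 and 1 adjusted over the list alone, median 0.47, camera adjusted p = 0.0260, adjusted p = 0.488 with an estimated correlation). Ier3 rose by 0.72 and Zfp36 by 0.79. Without breastfed 2 the adjusted p of that list was 0.0631.

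**Figure D2:**
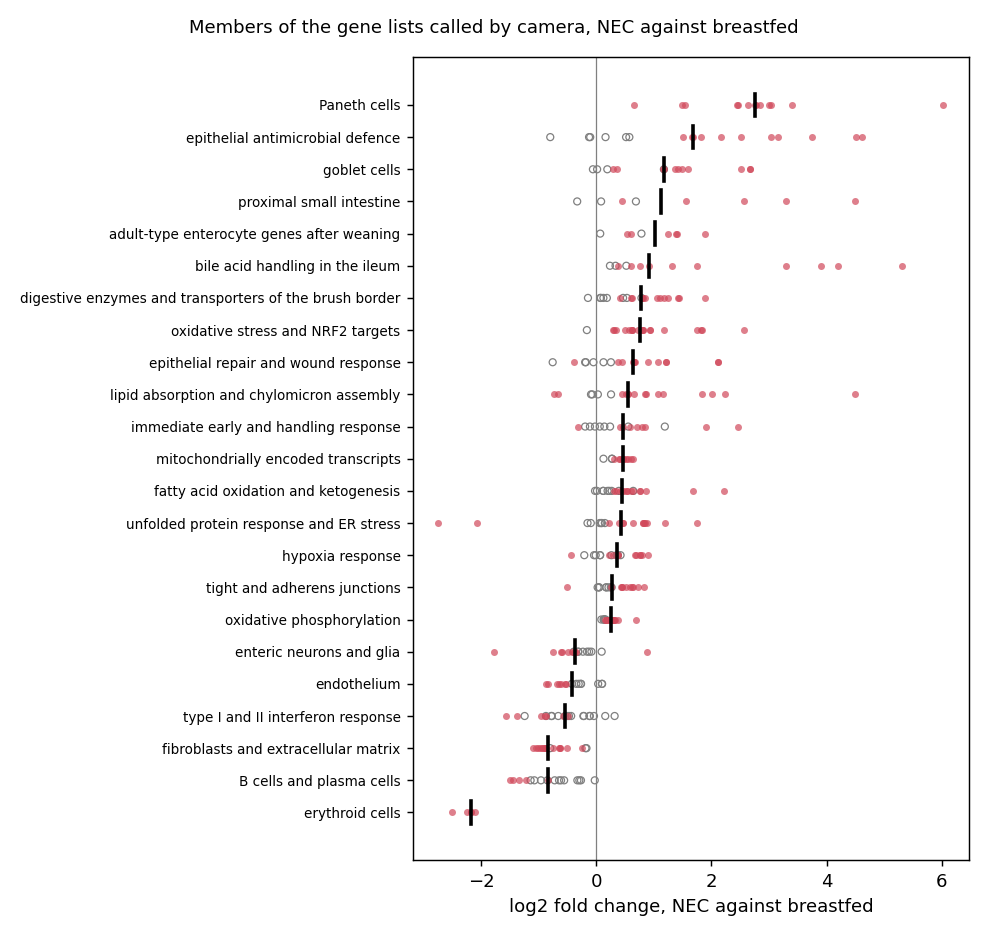
Log2 fold change of NEC against breastfed mice (horizontal axis) for the members of the 23 gene lists that camera called, where each point is a gene, filled when its adjusted p was under 0.05, and a bar marks the median. The Paneth cell list has the highest median, 2.75, and the erythroid list the lowest, -2.18.

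Fibroblast, enteric neuron, endothelial, erythroid and B cell genes were lower as lists in NEC mice. Fibroblast and extracellular matrix genes fell in 15 of 18 cases (16 adjusted over the list alone, median -0.84, camera adjusted p = 0.000368, adjusted p = 0.621 with an estimated correlation). Postn was at -1.09 (SE 0.22), Mfap4 at -1.02 (SE 0.23) and Lum at -0.90 (SE 0.19). Without breastfed 1, which held the highest score of this list, 6 of these 15 genes were still called and the median was -0.66. Enteric neuron and glia genes fell in 9 of 18 cases and Gfap rose (9 and 1 adjusted over the list alone, median -0.36, camera adjusted p = 0.0288, adjusted p = 0.621 with an estimated correlation). The receptor Ret was at -0.38 and Tubb3 at -0.60. Endothelial genes fell in 7 of 15 cases (7 adjusted over the list alone, median -0.43, camera adjusted p = 0.0340, adjusted p = 0.686 with an estimated correlation). Erg was at -0.87 and Cdh5 at -0.84. Of 16 smooth muscle genes Acta2 at -0.53, Ckb, Mylk and Pcp4 fell (4 adjusted over the list alone, median -0.06, camera adjusted p = 0.483). In each of these 4 genes breastfed 1 stood apart, above the other breastfed libraries. All 5 measured erythroid genes fell (5 adjusted over the list alone, median -2.18, camera adjusted p = 0.00576, adjusted p = 0.488 with an estimated correlation). Slc4a1, the anion exchanger of red cells, was at -2.51, and Hbb-bt fell beside those above. In the B cell list Cd79b at -1.50, Ebf1 at -0.84, Pax5, Ighm and Blk fell (5 of 17, 3 adjusted over the list alone, median -0.84, camera adjusted p = 0.0204, adjusted p = 0.686 with an estimated correlation). Pax5 was lost without NEC 1, NEC 4 or breastfed 1 (adjusted p = 0.0635, 0.0657 and 0.0608). T cell and innate lymphoid genes had a median of -0.79 over 16 members, of which 1 rose and 0 fell (1 adjusted over the list alone, camera adjusted p = 0.191). Leaving out 1 library ended the camera call of enteric neurons without breastfed 1 (adjusted p = 0.157) and of B cells without NEC 1 (0.0645). The endothelial call ended without breastfed 1, breastfed 3, breastfed 4 or NEC 2 (0.0537, 0.0946, 0.0536 and 0.0581), and with the replicate number as a block (0.0574).

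Among genes fixed for every comparison, Lcn2, which binds bacterial siderophores, rose by 1.66 (SE 0.39). Nos2 rose too (SE 0.36, adjusted p = 0.00358), beside Reg3g, Sis, Slc10a2 and Muc2 above. The bacterial sensor Tlr4 differed by 0.06 (SE 0.19), Tnf by 0.56 (SE 0.34, adjusted p = 0.197), and the stem cell genes Lgr5 by -0.11 (SE 0.16) and Olfm4 by 0.29 (SE 0.24), none of them past the threshold. Il1b, Il6 and Cxcl2 had too few counts to pass the filter, with NEC means of 0.752 ± 0.458, 0.0588 ± 0.0840 and 0.387 ± 0.200 CPM. Their highest counts in any library were 22, 3 and 9, and whether they changed stays open.

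What oral ST266 changes under the NEC protocol was asked by comparing that group with NEC. Camera with a preset correlation called 13 of 41 lists, and with an estimated correlation 0 (smallest adjusted p = 0.580). T cell genes had a median log2 change of 1.23 over 16 members (camera adjusted p = 2.33e-07, adjusted p = 0.706 with an estimated correlation), and B cell genes 0.91 over 17 members (adjusted p = 2.33e-07, adjusted p = 0.760 with an estimated correlation). Interferon response genes had a median of 0.43 (adjusted p = 3.43e-05, adjusted p = 0.760 with an estimated correlation) and mitochondrially encoded transcripts 0.24 (adjusted p = 2.33e-07, adjusted p = 0.580 with an estimated correlation). Paneth cell genes had a median of -0.85 over 13 members (adjusted p = 2.33e-07, adjusted p = 0.637 with an estimated correlation). Enteroendocrine, oxidative phosphorylation and cell death genes were also called higher (medians 0.20, 0.08 and 0.07). Unfolded protein response, stem cell, smooth muscle, fibroblast and erythroid genes were called lower (medians -0.18, -0.18, -0.20, -0.30 and -0.56). With an estimated correlation these 8 had adjusted p of 0.580 to 0.770, fry called 0 of the 41 lists (smallest adjusted p = 0.271), and no member of any list passed the test over all genes. Adjusted over the list alone, 3 Paneth, 3 unfolded protein response and 1 stem cell gene fell and 3 enteroendocrine genes rose. The mean T cell score lay at 2.09 to 2.61 in the oral libraries, at 0.412 to 1.94 in NEC and at 1.57 to 2.45 in breastfed libraries. Without oral 4 the fibroblast call ended (adjusted p = 0.0662), and the erythroid call ended without NEC 2, oral 1 or oral 4 (0.241, 0.160 and 0.247), with the replicate block (0.0638) and with a mean CPM of at least 1 (0.116).

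No single gene was called between oral ST266 and NEC by edgeR (0 of 15101, smallest adjusted p = 0.367), with 1146 genes at an unadjusted p under 0.05 where chance gives about 755. DESeq2 called 9 genes (3 higher, 6 lower) and limma-voom 0. The 95% interval of the fold change lay within 2-fold either way for 89.2% of genes and within 1.5-fold for 72.8%. Olfm4 differed by -0.58 (SE 0.24, adjusted p = 0.642), Lcn2 by -0.57 (SE 0.36), Tnf by -0.48 (SE 0.34), Sis by -0.39 (SE 0.25) and Slc10a2 by -0.29 (SE 0.36). In Sis a single library stood apart, and highest, in each group. NEC 4 was at 20.8 CPM (8.27 to 9.28 in the other NEC libraries) and oral 3 at 12.5 (7.54 to 8.21 in the other oral ones). Lgr5 differed by -0.19, Muc2 by -0.04, Nos2 by 0.01 and Tlr4 by -0.01. Reg3g differed by 0.84 (SE 0.69), which rested on oral 3, and without that library by -0.57 (adjusted p = 0.837).

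**Figure D3:**
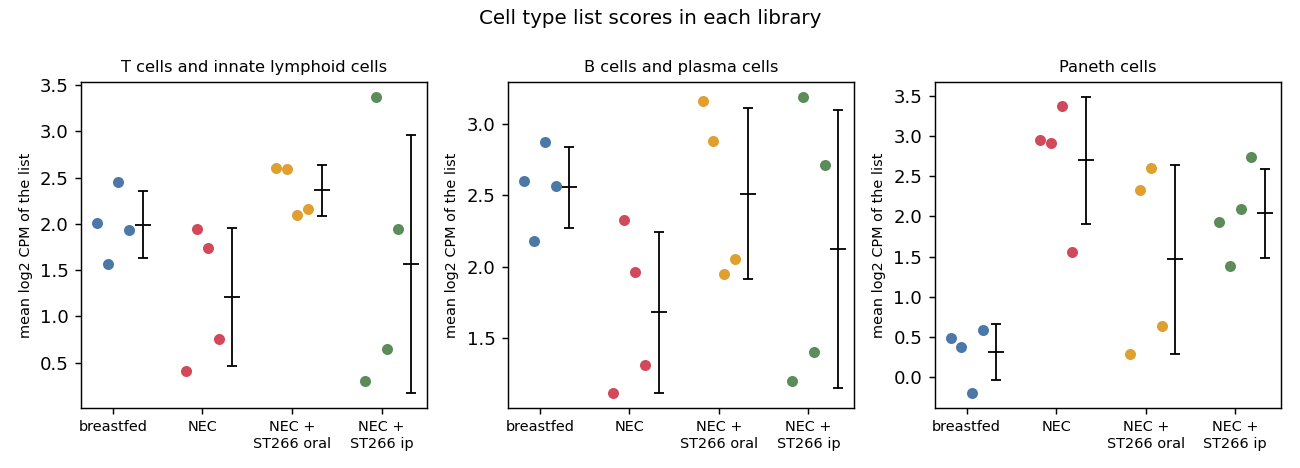
Mean log2 CPM of the T cell, B cell and Paneth cell lists (vertical axes, each with its own range) in each of the 16 libraries, by group (points), with the mean and SD of 4 libraries. The 4 oral ST266 libraries have T cell scores of 2.09 to 2.61, and the 4 intraperitoneal ones range from 0.304 to 3.37.

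Between intraperitoneal ST266 and NEC 4 genes were called, in a comparison where the agent and its injection cannot be told apart. Anxa8, an annexin (chromosome 14, 34085981 to 34100571), rose by 0.73 (SE 0.12, adjusted p = 0.0492), from 19.4 ± 2.29 to 32.3 ± 5.55 CPM, where breastfed mice had 67.4 ± 8.93 CPM (n = 4 each). The zinc finger gene Zc3h7a (chromosome 16, 11136592 to 11176393) fell by 0.48 (SE 0.08, adjusted p = 0.0428), from 82.1 ± 8.18 to 58.9 ± 2.63 CPM, with 56.5 ± 2.37 CPM in breastfed mice. Snrnp48, a part of the minor spliceosome (chromosome 13, 38204938 to 38227665), fell by 0.39 (SE 0.06, adjusted p = 0.0304), from 35.3 ± 1.79 to 26.9 ± 0.501 CPM, with 22.5 ± 0.133 CPM in breastfed mice. Nfat5, the transcription factor of the response to osmotic stress (chromosome 8, 107293470 to 107379517), fell by 0.41 (SE 0.06, adjusted p = 0.0304), from 103 ± 6.58 to 77.9 ± 3.03 CPM, with 97.1 ± 4.87 CPM in breastfed mice. Between NEC and breastfed mice Anxa8, Zc3h7a and Snrnp48 had changed by -1.79, 0.54 and 0.65. Both comparisons use the same NEC libraries, so a return was not tested for these genes.

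This count of 4 (of 15101 genes, with 2223 at an unadjusted p under 0.05) moved with the libraries and the tool. It was 0 without NEC 1, NEC 2, NEC 4, intraperitoneal 1, 2, 3 or 4, 2 without NEC 3, and 128 without breastfed 1. That library belongs to neither group, and leaving it out changes the estimate of the spread and the genes tested (15192 in place of 15101). DESeq2 called 322 genes, limma-voom 142 and edgeR 60 when fitted to the 8 compared libraries alone, of which 193, 109 and 53 were lower, and with the replicate number as a block 7 were called. Asked for a change beyond 1.5-fold, 0 genes were called, and Anxa8 was lost with DESeq2 size factors (adjusted p = 0.0501). Of the fixed genes, Sis differed by -0.77 (SE 0.26, adjusted p = 0.197), Slc10a2 by -0.71 (SE 0.36), Reg3g by -0.47 (SE 0.69), Nos2 by -0.47 (SE 0.34) and Tnf by -0.45 (SE 0.34). Olfm4 differed by -0.37, Tlr4 by 0.19, Lcn2 by -0.10, Muc2 by 0.10 and Lgr5 by -0.05. The difference in Sis leans on NEC 4, at 20.8 CPM (8.27 to 9.28 in the other NEC libraries).

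Camera called 10 of 41 lists between intraperitoneal ST266 and NEC, and with an estimated correlation 0 (adjusted p = 0.973 for each of the 10). Higher were interferon response (median 0.41, adjusted p = 0.0102), B cell (0.62, adjusted p = 0.0356), TLR4 and NF-kB (0.14), oxidative phosphorylation (0.13, adjusted p = 2.31e-05), neonatal enterocyte (0.21) and enteroendocrine genes (0.14). Lower were proliferation (-0.19, adjusted p = 0.00995), stem cell (-0.20), smooth muscle (-0.28, adjusted p = 0.00278) and fibroblast genes (-0.24). Fry called 0 lists (smallest adjusted p = 0.463), and no list member passed over all genes, while 2 TLR4 genes rose and 1 neonatal enterocyte gene fell when adjusted over the list alone. The T cell score of these libraries ranged from 0.304 to 3.37 and its list was not called. Each of these calls except oxidative phosphorylation and smooth muscle was lost in at least 1 fit without a library: without intraperitoneal 2 the B cell median was 0.22 (adjusted p = 0.818) and the interferon median 0.19 (0.250), and without intraperitoneal 3 the fibroblast median was -0.12 (0.552) and the proliferation median -0.09 (0.178). Other libraries that ended 1 or more of these calls were NEC 1, NEC 2, NEC 3, NEC 4 and intraperitoneal 4, with adjusted p of 0.0521 to 0.818. The B cell call also ended with a mean CPM of at least 1 (adjusted p = 0.0662). Intraperitoneal 2, without which the B cell and interferon calls ended, also stood apart in the adipocyte and mesentery score, at 4.09 (2.32 to 2.40 in the other intraperitoneal libraries).

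Both routes together, as the mean of the 2 ST266 groups against NEC, gave lists that were called in 1 route or both. T cell genes had a median of 1.05 (camera adjusted p = 0.000373), B cell genes 0.75 (adjusted p = 0.000156), interferon genes 0.48 (adjusted p = 0.000174) and Paneth cell genes -0.90 (adjusted p = 0.000233). Of 41 lists 13 were called, 0 with an estimated correlation (smallest adjusted p = 0.870) and 0 by fry (smallest adjusted p = 0.249). By edgeR 0 genes were called (smallest adjusted p = 0.147), with 1874 at an unadjusted p under 0.05, 138 by DESeq2 and 8 by limma-voom, and 2 by edgeR without breastfed 1. The calls of the cell death, unfolded protein response and proliferation lists (medians 0.04, -0.11 and -0.11) ended in fits without NEC 2, NEC 3, NEC 4, oral 1, oral 3, oral 4, intraperitoneal 2 or intraperitoneal 3, each in 1 or more of them, with adjusted p of 0.0505 to 0.376.

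Whether ST266 moved the ileum as a whole toward the breastfed state was measured by an axis score per library, with 0 at the breastfed and 1 at the NEC mean of 5005 to 6236 genes that differed between those groups. NEC libraries scored 0.944 ± 0.125, oral ST266 libraries 0.914 ± 0.0683 and intraperitoneal ones 0.935 ± 0.143 (SD, n = 4), and breastfed libraries, scored the same way, 0.0697 ± 0.189. The difference from NEC was -0.0303 for the oral route (two-sided exact permutation p = 0.771, adjusted p = 0.971) and -0.00902 for the intraperitoneal route (exact permutation p = 0.971, adjusted p = 0.971), over 70 assignments of which the smallest possible p is 0.0286. Both differences were smaller than the spread between replicates. Left out in turn, single libraries moved the oral difference between -0.0592 and -0.000976 and the intraperitoneal one between -0.0609 and 0.0533.

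**Figure D4:**
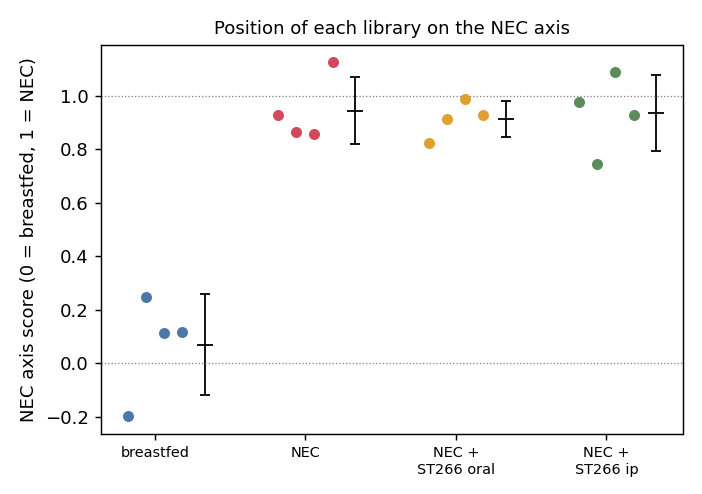
NEC axis score (vertical axis, 0 at the breastfed and 1 at the NEC mean) of each of the 16 libraries, by group (points), with the mean and SD of 4 libraries. All 12 libraries of the NEC protocol lie between 0.746 and 1.13, and the breastfed ones between -0.197 and 0.246.

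For genes that NEC had changed, single halvings of the NEC libraries gave changes to both sides of 0 with ST266. With NEC libraries halved so that no library served both comparisons, the median change of these genes with oral ST266, signed by their NEC change, was -0.0091 on the log2 scale (6 halvings, -0.0501 to 0.0322), beside a median NEC change of 0.585. With intraperitoneal ST266 it was -0.0054 (-0.0434 to 0.0361), beside 0.577. Data simulated without an ST266 effect gave -0.00096 (20 simulations, -0.00497 to 0.00258) and -0.00060 (-0.00348 to 0.00312). These simulated ranges are of means over 6 halvings, with genes drawn independently. They are therefore narrower by construction and cannot be set against the range of single halvings. Both means are smaller than the SD between halvings (0.0384 and 0.0390). This also held for genes that NEC changed at an FDR of 0.01 (-0.0182 and -0.0279), with DESeq2 size factors (-0.00983 and -0.00323) and with a mean CPM of at least 1 (-0.00855 and -0.00276). With the same NEC libraries in both comparisons the values were -0.0236 and -0.0160, where simulated data gave -0.0279 and -0.0273. The changes of the 2 routes against separate NEC libraries correlated across genes at 0.202 (0.134 to 0.293), against 0.0288 in simulated data (-0.0595 to 0.11, again of means over 6 halvings), where genes are not independent replicates. For a permutation, the covariance of the routes was computed anew from differences of mean log2 CPM, in place of edgeR changes, again with halved NEC libraries. It was 0.01815, and all 17325 assignments of the 12 libraries to 3 groups gave a two-sided exact permutation p of 0.123.

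How far treated mice differed from breastfed ones was read from the same ranking, with Reg3g, Saa3 and Reg3b again among the largest rises. With oral ST266, Reg3g rose by 5.46 (SE 0.89), Saa3 by 4.91, Reg3b by 4.60, Fabp6 by 4.18, Duox2 by 3.67 and the chemokine Ccl20 by 3.66 (SE 0.41, adjusted p = 1.07e-05). The size of 2 of these rises depended on oral 3: without it Reg3g rose by 4.05 (adjusted p = 0.000108) and Reg3b by 3.22 (adjusted p = 1.04e-05). With intraperitoneal ST266, Saa3 rose by 5.34 (SE 0.68), Reg3g by 4.14, Reg3b by 3.71, Ccl20 by 3.63 and Slc10a2 by 3.19, and so did Rps7-ps3 by 3.48, a pseudogene whose reads cannot be told from those of its parent gene with certainty. The erythroid genes Hbb-b1 and Alas2 fell in both groups, Hbb-b1 by 2.75 and 2.40 and Alas2 by 2.72 and 2.39 on the log2 scale. Fibroblast genes fell in 17 and 15 of 18 cases (medians -1.06 and -1.02), oxidative phosphorylation genes rose in 23 and 24 of 24 cases (0.35 and 0.36), and Paneth cell genes rose in 5 and 10 of 13 cases (1.63 and 1.86) for the oral and intraperitoneal route. Camera called 21 and 23 lists, 0 of them with an estimated correlation (smallest adjusted p = 0.476 and 0.456), and fry 26 and 29. Adjusted over the list alone the 3 pairs of counts were 18 and 17, 24 and 24, and 7 and 11. In the oral group the Paneth call ended without breastfed 3, oral 2 or oral 3 (adjusted p = 0.0677, 0.0996 and 0.124).

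By edgeR 6812 genes were called with oral ST266 against breastfed (3457 higher, 3355 lower, 891 over 2-fold) and 7379 with intraperitoneal ST266 (3636 higher, 3743 lower, 1018 over 2-fold). Of the genes higher in NEC, 85.5% were also higher with oral and 84.4% with intraperitoneal ST266, and of those lower in NEC 79.0% were also lower with each route. Shared breastfed libraries can raise these shares. With the breastfed libraries halved, the shares were 72.3% and 72.2% for higher and 62.3% and 63.6% for lower genes, where independent calls would share 470, 495, 405 and 456 of the 2651 higher and 2463 lower genes on average. Halving also leaves fewer breastfed libraries and fewer calls per comparison, so the drop cannot be put down to sharing alone. Data simulated without a group difference, with shared breastfed libraries, gave 0 shared calls in 20 simulations. Such data leave few or no calls to share, so this count cannot show how far shared libraries raise the shares. The simulated log2 changes of NEC and of each route still correlated across genes at 0.502 (oral) and 0.507 (intraperitoneal). Measured values were 0.880 and 0.869 with shared breastfed libraries, and 0.712 and 0.707 with these halved.

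The routes were compared directly with each other, intraperitoneal against oral, and camera called 8 lists, 0 of them with an estimated correlation (adjusted p = 0.877 for each). Genes of the unfolded protein response were higher with the intraperitoneal route (median 0.16 over 20 members, camera adjusted p = 0.000160), as were neonatal enterocyte genes (0.22), Paneth cell genes (0.36) and macrophage genes (0.24). T cell (-0.28), B cell (-0.29), proliferation (-0.13) and mitochondrially encoded transcripts (-0.15, adjusted p = 0.000269) were lower. Fry called 0 lists in 1 direction (smallest adjusted p = 0.667) and, for changes in either direction, the unfolded protein response (adjusted p = 0.0183), and 5 unfolded protein response genes rose when adjusted over the list alone. By edgeR 0 genes differed between the routes (smallest adjusted p = 0.102), with 1201 at an unadjusted p under 0.05, 27 by DESeq2 and 0 by limma-voom, and 1 by edgeR without oral 3. Leaving out 1 library ended 5 of the 8 list calls. The B cell call ended without oral 1, oral 2, intraperitoneal 1 or intraperitoneal 3 (adjusted p = 0.327, 0.134, 0.611 and 0.334) and with the replicate number as a block (0.0560), and the T cell call without intraperitoneal 1 or 3 (0.215 and 0.0634). The Paneth call ended without oral 1, oral 4 or intraperitoneal 4 (0.327, 0.247 and 0.183), and the macrophage call without oral 4, intraperitoneal 2 or intraperitoneal 4 (0.418, 0.381 and 0.0570). The proliferation call ended without intraperitoneal 1, 2 or 3 (0.0933, 0.109 and 0.598), and without oral 2 its median changed sign, to 0.03 (0.954).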

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

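The checks of single libraries and the test of the routes against each other were planned, and the choice of genes listed here includes members of lists named after their values were seen. A library was singled out when its gap to the nearest of the other 3 libraries of its group was a larger share of the group's range than the 95% critical value of Dixon's test, which happened in 68 of 828 groups checked (8.2%), where chance gives about 1 in 20. Breastfed 1 accounted for 21 of them, and the genes and lists overlap, so these are not independent. Gene levels are in CPM and list scores in mean log2 CPM, each followed by the range of the other 3 libraries where it is given.

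Breastfed 1 had more muscle and pacemaker cell transcripts and fewer epithelial ones than the other breastfed libraries. Its smooth muscle score was 8.43 (7.66 to 7.75 in the others) and its score for interstitial cells of Cajal 4.54 (3.84 to 3.86), with Acta2 at 3755, Mylk at 2231, Kit at 90.2, Ckb at 434, Pcp4 at 62.9, Smoc2 at 160.5, Scg3 at 25.7, Dclk1 at 39.1 and Plin4 at 25.5. It was lowest in the scores of the brush border at 6.65 (7.29 to 7.41), fatty acid oxidation at 6.07, oxidative phosphorylation at 7.23 and cell death genes at 4.28, and in Mep1b at 145.3 (240.0 to 258.4), Cox5a at 97.8 and Tmigd1 at 51.97. The clock genes Dbp at 46.3, Hlf at 29.1 and Per3 at 33.8 were highest there.

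Oral 3 had the most Reg3g at 557.6 (45.2 to 98.5 in the others), Reg3b at 1998 (224.1 to 319), Saa3 at 55.5, Sis at 12.5 and Krt7 at 279.9, and the least Hlf at 7.13 and Pcp4 at 22.7. Oral 4 stood out in the fatty acid oxidation score at 7.14 and Nr1d1 at 14.0, oral 2 in Muc2 at 333.9 and Cdk1 at 26.4, and oral 1 in Car3 at 1.68. In the NEC group, NEC 4 was highest in the oxidative phosphorylation score at 7.72, Sod1 at 346.8, Sis at 20.8 (8.27 to 9.28), Cyc1 at 184.7, Vegfa at 109.7 and Trib3 at 2.95, and lowest in Mfap4 at 44.0, Tef at 50.8 and Per3 at 13.5. NEC 1 was apart in Rgmb at 101.4 and Dnajb1 at 39.1, NEC 2 in Slc4a1 at 0.856, and NEC 3 in Clca1 at 128.3 and Kit at 51.3.

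Intraperitoneal 2 held 1.29% of its counts without a gene name (1.15 to 1.16 in the others), had a score of 4.09 for adipocytes and mesentery (2.32 to 2.40), with Plin1 at 1.87, and was lowest in the scores of adult-type enterocytes at 5.27 and goblet cells at 4.43, and in Acadvl at 128.7, ATP6 at 5070 and Padi4 at 5.10. Intraperitoneal 1 stood apart in the cholesterol synthesis score at 6.43, Slc10a2 at 25.9, Zfp36 at 233.4 and Egfr at 23.6, intraperitoneal 3 in Notum at 4.54, Lipe at 51.1 and Cyp3a11 at 1.17, and intraperitoneal 4 in Hlf at 15.1. Breastfed 2 was highest in Reg3g at 8.31, and breastfed 4 was apart in Vegfa at 53.3, Traf6 at 47.8, Slc12a2 at 62.8 and Il6 at 0.0548, a value of a single count or so.

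The effect of ST266 differed between routes in 8 lists by the direct comparison with camera. Adjusted p was 0.000160 for the unfolded protein response, 0.000324 for neonatal enterocytes, 0.0102 for Paneth cells, 0.0205 for macrophages, 0.00216 for T cells, 0.0428 for B cells, 0.0444 for proliferation and 0.000269 for mitochondrially encoded transcripts. None of the 8 was called with an estimated correlation (adjusted p = 0.877) or by fry in 1 direction (smallest adjusted p = 0.667), while fry for either direction called the unfolded protein response (adjusted p = 0.0183). For these lists no technical or biological explanation was tested.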

How the results depend on the processing

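The fits without breastfed 1 for comparisons without breastfed mice, and those with the B and T cell score as a covariate, were chosen only after the results had been seen. The comparisons with breastfed mice kept their counts of genes within 1.5 times under all alternatives except the test beyond 1.5-fold, which called 580 genes for NEC, 602 for oral and 707 for intraperitoneal ST266, fewer because it asks for larger changes. Under the other settings, the covariates and fits without 1 library included, NEC against breastfed gave 5599 to 7168 genes, oral ST266 5947 to 7296 and intraperitoneal ST266 6274 to 7862, with 47.7% to 52.8% of them higher, so which side had more genes depended on the setting. With an estimated correlation camera kept 0 of their 23, 21 and 23 list calls. Fry, which asks a different question, called 25, 26 and 29 of the 41 lists in 1 direction. Of 109 called genes named for NEC against breastfed, 108 kept their call with DESeq2 and 108 with the replicate block, and of 872 tests without 1 library 850 kept it and 22 lost it.

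Counts against NEC depended on the tool. DESeq2 called 9 genes for oral, 322 for intraperitoneal and 138 for the mean of the routes, and 27 between the routes, and limma-voom 142 for intraperitoneal and 8 for the mean. Intraperitoneal ST266 against NEC gave 7 genes with the replicate block, 60 in a fit of the compared groups alone and 0 beyond 1.5-fold. With the B and T cell score as a covariate it gave 8, and with the score centred within groups oral ST266 gave 99, intraperitoneal 32, the mean of the routes 61 and the routes against each other 14. The cause was not tested for these, other than that beyond 1.5-fold larger changes are asked for.

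Without 1 library, intraperitoneal ST266 against NEC ranged from 0 (without NEC 1, among others) to 128 genes (without breastfed 1), the mean of the routes from 0 to 2 (without breastfed 1), the routes against each other from 0 to 1 (without oral 3) and oral ST266 against NEC stayed at 0. The proliferation list between the routes ranged from -0.28 (without intraperitoneal 4) to 0.032 (without oral 2), where its sign reversed. The agreement of the routes moved from a correlation of 0.202 to 0.600 and a covariance of 0.0269 to 0.0535 when the same NEC libraries served both routes, which adds their shared error. In that setting, data simulated without an ST266 effect gave a correlation of 0.512 (0.414 to 0.576) and a covariance of 0.03085 (0.0244 to 0.0377). With the replicate number as a block the axis differences were -0.0303 and -0.00902 (exact permutation p = 0.750 and 1, by sign flips of the paired differences). With 4 pairs such flips cannot give a p under 0.05, so this setting could not have called a difference. Differences of the axis score from NEC ranged from -0.0541 to -0.0299 (oral) and -0.0661 to -0.00413 (intraperitoneal) under the other settings fixed beforehand. For the agreement, a stricter threshold for the changed genes could not apply, since all genes enter. Depth limits what can be said of Il1b, Il6 and Cxcl2.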

Other observations

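The tests of 2-fold effects, of the share of the wall, of the time of day, of the principal component and of the covariate as it is were chosen only after the results had been seen. The remaining lists were not called between NEC and breastfed mice, and in several of them members changed in both directions. Of 5 genes of interstitial cells of Cajal, Kit at -0.46 and Prkcq at -0.43 fell (4 adjusted over the list alone, camera adjusted p = 0.169), and of 18 macrophage genes Csf1r at -0.35 and Cx3cr1 at -0.90 (2 adjusted over the list alone, 0.214). Breastfed 1 stood apart in the score of the Cajal cell list, at 4.54 (3.84 to 3.86 in the other breastfed libraries), and in Kit. It was also apart, and highest, in Smoc2, Scg3 and Dclk1, named below as lower in NEC. Of 15 stem cell genes Znrf3 at -0.69, Rgmb at -0.50, Ephb3, Smoc2 and Tnfrsf19 fell and Aqp4 and Slc12a2 rose (5 and 2 adjusted over the list alone, median 0.10 and mean -0.04, camera adjusted p = 0.978 in the upward direction). Enteroendocrine genes rose in 5 of 16 cases, Tph1 at 1.46, Gcg at 1.39, Neurod1, Sct and Sst, and Scg3 fell (5 and 1 adjusted over the list alone, median -0.06, mean 0.21, camera upward, adjusted p = 0.555). In the cholesterol synthesis list 5 of 20 genes fell, Insig1 at -1.03 and Srebf2 at -0.38 among them (4 adjusted over the list alone, median 0.01, mean -0.11, camera downward, adjusted p = 0.555). Aurkb at -0.49 and Cdk1 at -0.51 fell among 20 proliferation genes (0 adjusted over the list alone, 0.264), Dclk1 at -0.70 among 9 tuft cell genes (1 adjusted over the list alone, 0.471) and Padi4 at -0.56 among 8 neutrophil genes (1 adjusted over the list alone, 0.571). Of lists for other tissues, adipocytes had 3 genes that rose (Cidec, Lipe and Plin4) and 2 that fell, Car3 at -2.93 and Plin1 at -2.58 (of 11, 3 and 2 adjusted over the list alone, median -0.16, mean -0.64, camera upward, adjusted p = 0.978). Mesothelium had Krt19 and Krt7 higher (of 10, 2 adjusted over the list alone, median -0.06, mean 0.08, 0.391), and the pancreas list had 1 testable gene, not called (1 adjusted over the list alone, 0.437). Of 6 colon genes 2 rose, Slc26a3 at 1.60 among them, and B3galt5 at -0.74 fell (2 and 1 adjusted over the list alone, 0.483). B3galt5 was lost with DESeq2 (adjusted p = 0.0636), with the replicate number as a block (0.0530), and without NEC 1, NEC 2, breastfed 1 or breastfed 4 (0.0941, 0.0551, 0.118 and 0.0648).

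Of 8 genes driven by the circadian clock, looked at after their values had been seen, 7 were lower in NEC mice, and no enrichment was tested. Nr1d1 fell by 1.78 (SE 0.27, adjusted p = 9.29e-05), Bhlhe41 by 1.42, Dbp by 1.27, Hlf by 0.92, Tef by 0.71 and Nr1d2 by 0.70 on the log2 scale, Ciart also fell, and Per3 at -0.26 was not called. On the third principal component (7.76% of the variance) the 4 NEC libraries lay at -23.9 to -14.6 and the 8 ST266 libraries at -4.35 to 19.5, a difference of 25.3 (exact permutation p = 0.00202, two-sided, the smallest that 495 assignments can give, 1 of 4 components looked at). Breastfed libraries lay at -16.0 to 12.3 on it.

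Few genes were called between ST266 and NEC, 0 for the oral and 4 for the intraperitoneal route. Missed changes of 2-fold or more cannot be told apart from a lack of such changes. The 95% intervals lay within 2-fold for at least 87.9% of genes in either route, but for only 1 of 16 T cell, 1 of 17 B cell and 1 of 13 Paneth cell genes. Spread between libraries from their content of lymphoid tissue cannot be told apart from an ST266 effect, because the B and T cell score differs with the oral group. With that score as a covariate at most 8 genes were called in a route, and with the score centred within groups, which removes spread by construction, 99 for oral and 32 for intraperitoneal ST266, of which 95 and 9 follow the score at a correlation above 0.7. Effects of ST266 stay open, in variable genes also those over 2-fold.

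Lower fibroblast and matrix genes in NEC mice were weighed against 3 technical explanations. A smaller share of the whole wall below the epithelium would lower smooth muscle alike, but the fibroblast score minus the smooth muscle score differed by -0.63 (NEC 0.12 ± 0.33, breastfed 0.75 ± 0.30, n = 4, exact permutation p = 0.0286, two-sided, and 0.0286 also without breastfed 1). This is the smallest p these assignments can give, and both list medians were known when the test was chosen. Scores of other wall tissues were lower too: enteric neurons and glia at -0.33 (exact permutation p = 0.0286) and endothelium at -0.40 (0.0571). A smaller share of wall layers other than muscle therefore cannot be told apart by this test. GC content or gene length bias left 88.6% of the median once its trend was removed. The breastfed library that stands apart met the criterion set beforehand for this explanation, that most called members lose their call without it. Without breastfed 1, 6 of the 15 called members stay called, against 15, 13 and 12 without breastfed 2, 3 and 4, with the median at -0.66 in place of -0.84 and the SE at 0.23 in place of 0.22. A change of the stroma with the NEC protocol is a further candidate, a hypothesis found and tested on the same libraries. It was not told apart from a smaller share of single wall layers.

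Lower clock output genes could reflect another time of day of collection, which the labels do not give. Genes of the opposite phase would then rise, and their median was 0.17 (SE 0.31 over 5 genes), with Npas2 at 0.57 and Cry1 at 0.33 higher and Arntl at -0.48 and Nfil3 at -0.76 lower. The time of day and the NEC protocol cannot be told apart by this test, since its members went both ways. Without breastfed 1, which has the highest Dbp, Hlf and Per3, 7 of the 8 clock output genes still fell.

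Whether other groupings of the libraries give counts as large was asked with all other splits of the same libraries. NEC against breastfed called 6642 genes and the highest other of 35 splits 0 (1 split as large), oral ST266 against breastfed 6812 and 2 (1 split), and intraperitoneal ST266 against breastfed 7379 and 1090 (1 split). In these comparisons the labels gave more genes than every other split, and 1 of 35 is the strongest result that so few splits can give. The other splits mix both groups, which raises the spread, so low counts there were partly built in. The split with 1090 genes sets breastfed 2 with intraperitoneal 1, 3 and 4 against the rest. It exchanges only breastfed 2 and intraperitoneal 2, so part of the difference between the groups remains in it. Chance is not excluded for intraperitoneal ST266 against NEC, with 4 genes, as 2 of 35 splits gave as many. The other of these called 159 genes and sets NEC 1, NEC 4, intraperitoneal 1 and intraperitoneal 3 against NEC 2, NEC 3, intraperitoneal 2 and intraperitoneal 4, so a structure of the samples not given by the labels is present here. For comparisons with 0 genes every split is as large by definition, so these shares say nothing about chance. They were 35 of 35 for oral ST266 against NEC (highest other 1), 100 of 100 drawn for the mean of the routes (highest other 51) and 35 of 35 for the routes (highest other 1), by edgeR, with the unadjusted counts 1146, 1874 and 1201 and the DESeq2 counts 9, 138 and 27.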
